A study of Mus musculus with 168 samples.

How the data were processed

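The samples were cortex of C57BL/6 mice heterozygous for 1 of 6 Htt knock-in alleles, or wild type, at 2, 6 and 10 months, with 8 libraries in each of the 21 groups. Per the labels, RNA was extracted from flash-frozen tissue with a column kit, checked on a Bioanalyzer, polyA-selected and sequenced on Illumina HiSeq instruments. The labels also state that mice were housed with others of their own allele, and wild types with Q20. Housing and allele therefore cannot be told apart in the slopes or in the comparisons of longer alleles with Q20, at any age. The authors deposited estimated counts per gene for each library, of which 17.7% were not whole, as arises when reads are shared between genes, and which were not scaled to a common total. The authors deposited FPKM values for the same libraries as a second table, scaled by gene length and library size. CASAVA 1.8.2 is named in the submitters' processing notes, while the aligner, the quantification tool, the genome build and the annotation behind the counts are not given in the sources used here.

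Each table held 39179 Ensembl gene IDs, of which 37607 were matched to a symbol in GENCODE M21 (GRCm38), and the IDs without a symbol held 0.32% of the counts. Positions are those of GENCODE M21. The estimated counts were rounded to whole numbers and summed to between 29338750 and 47353396 per library. No pair of the 588 library pairs within groups had counts that differed by no more than counting error, with a chi-square per degree of freedom of at least 3.37. Totals are of estimated counts after alignment, so that errors and tests of single genes here rest on the spread between libraries and not on counting error alone.

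Genes with low counts were left out with filterByExpr of edgeR 4.0.16 by genotype (a minimum count of 10 and a minimum total of 15), and libraries were scaled by TMM. Quasi-likelihood F tests, with alternatives on both sides (estimateDisp, glmQLFit with robust set to true, glmQLFTest) were run with sex as a covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Errors of log2 differences are standard errors from the estimate and the square root of F. The slope along CAG length was fitted per age to the 48 knock-in libraries with the nominal CAG length, in units of 100 repeats, and without the wild types. Each allele and wild type was compared with Q20 in a fit of all genotypes of an age. Differences of slopes between ages and sexes were tested as interaction terms, and Q20 at 10 months was compared with Q20 at 2 months.

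Gene lists of cell type markers and pathways, 32 in number, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives not said to be added. Lists with at least 5 tested genes were tested along the slope with camera of limma 3.58.1, with a preset correlation of 0.01 and with a correlation estimated from the data, and with fry, on log2 CPM with a prior count of 2. The list p-values were adjusted over the 31 lists tested, because 1 list, of the alpha and gamma protocadherins, had fewer than 5 tested genes. A list of liver transcripts was added after the values were seen, and its p-values were not adjusted. Named genes were the 10 rising and 10 falling genes with the smallest p of each slope, 5 each way for Q175, wild type and slope differences, 2 each way for the other alleles, 8 each way for Q20 with age, up to 4 members of each list with the smallest p, Htt, and the sex-linked genes, leaving out gene models with clone names. Some genes that this rule names are not given in the text.

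The alternatives tried were DESeq2 1.42.0 as the test, its size factors in edgeR, no filter on low counts, no sex term, the replicate number as a block, the L token of the library name as a term for the slopes at 2 and 10 months, the rank of the allele in place of CAG length, fits without Q175, with the wild types added, with wild type as the reference or with only the 2 groups compared, limma on log2 FPKM with pseudocounts of 0.1 and 1 for genes with a mean FPKM of at least 0.1, and leaving out each of the 48 libraries of a slope in turn. Added after the values were seen were fits without 9 libraries whose median correlation with the others of their age was under 0.99, without Q80 male 1 of 2 months, and with the liver level as a covariate. Calls were compared with those from up to 100 splits of the libraries into groups, the real one included and the others drawn at random with a fixed seed. On simulated counts with 200 changed genes, the slope test at 10 months found 71.6% of genes with a slope of 0.2 and 98.5% of those with 0.8, and false calls made up 2.8% to 6.9% of calls over the simulated comparisons. The simulated counts were drawn independently for each gene, without outlying libraries or library series. These shares therefore need not hold for the deposited libraries. The work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.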

Results

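Messenger RNA was sequenced from the cortex of mice in which the Huntington's disease gene Htt carried a knocked-in CAG repeat on 1 allele. The alleles had nominal lengths of 20, 80, 92, 111, 140 and 175 repeats (Q20 to Q175) and were measured beside wild-type (WT) mice at 2, 6 and 10 months of age. Each of the 21 groups held 8 libraries, and 83 libraries in all came from females and 85 from males. The estimated counts assigned to genes summed to between 29338750 and 47353396 per library. The spread between libraries, as a biological coefficient of variation, was 0.114 at 2 months, 0.079 at 6 months and 0.105 at 10 months among the knock-ins. The p-values of single genes measure the spread between these libraries. Those of Fisher's exact tests count genes as independent units and hold no spread between libraries. Those of camera with its preset correlation of 0.01 take the genes of a list as nearly independent. Slopes are log2 changes per 100 CAG repeats over the 48 knock-in libraries of an age, given with the standard error (SE). Group levels are CPM, counts scaled to a common library total, with the standard deviation (SD).

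Xist, the RNA that coats the inactive X chromosome, lay between 544 and 1590 CPM in the female libraries and at most 2.52 CPM in the male ones. The Y-linked helicase gene Ddx3y lay at 42.4 to 117 CPM in 84 male libraries. The Q80 male 1 library of 2 months had 0 CPM of Ddx3y, Eif2s3y and Uty and 1.02 CPM of Xist, and so had neither signal.

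Htt itself, which encodes huntingtin, fell along the series at 6 and 10 months. At 6 months Htt (ENSMUSG00000029104, GRCm38 chromosome 5 from 34761740 to 34912534) stood at 207 ± 11 CPM (SD, n = 8) in Q20, 183 ± 6.65 in Q140 and 154 ± 15.8 in Q175, with 200 ± 4.13 in WT, while Q80 (225 ± 5.24) and Q92 (226 ± 9.44) lay above Q20. At 10 months it stood at 198 ± 22.1 CPM in Q20, 166 ± 28.5 in Q140 and 158 ± 11.4 in Q175, with 195 ± 7.95 in WT, and Q80 (220 ± 16.1) and Q92 (203 ± 21.6) again had higher means than Q20. The slopes of Htt were -0.30 ± 0.05 at 6 months (adjusted p = 4.6e-05) and -0.27 ± 0.06 at 10 months (adjusted p = 0.0033). At 2 months the slope of Htt was -0.23 ± 0.07 and did not pass (adjusted p = 0.84), although all 8 Q175 libraries lay under the Q20 median at each age. In Q175 against Q20, Htt differed by -0.43 ± 0.04 at 6 months (adjusted p = 6.8e-12) and -0.33 ± 0.08 at 10 months (adjusted p = 0.0046). Without Q175 the slope of Htt was -0.12 at 6 months and -0.20 at 10 months and no longer passed. Without 9 libraries that correlated least with the others of their age, the 2-month slope of Htt, -0.26, passed, as did the 2-month differences of Q140 (-0.24) and Q175 (-0.36) from Q20 in Htt.

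**Figure D1:**
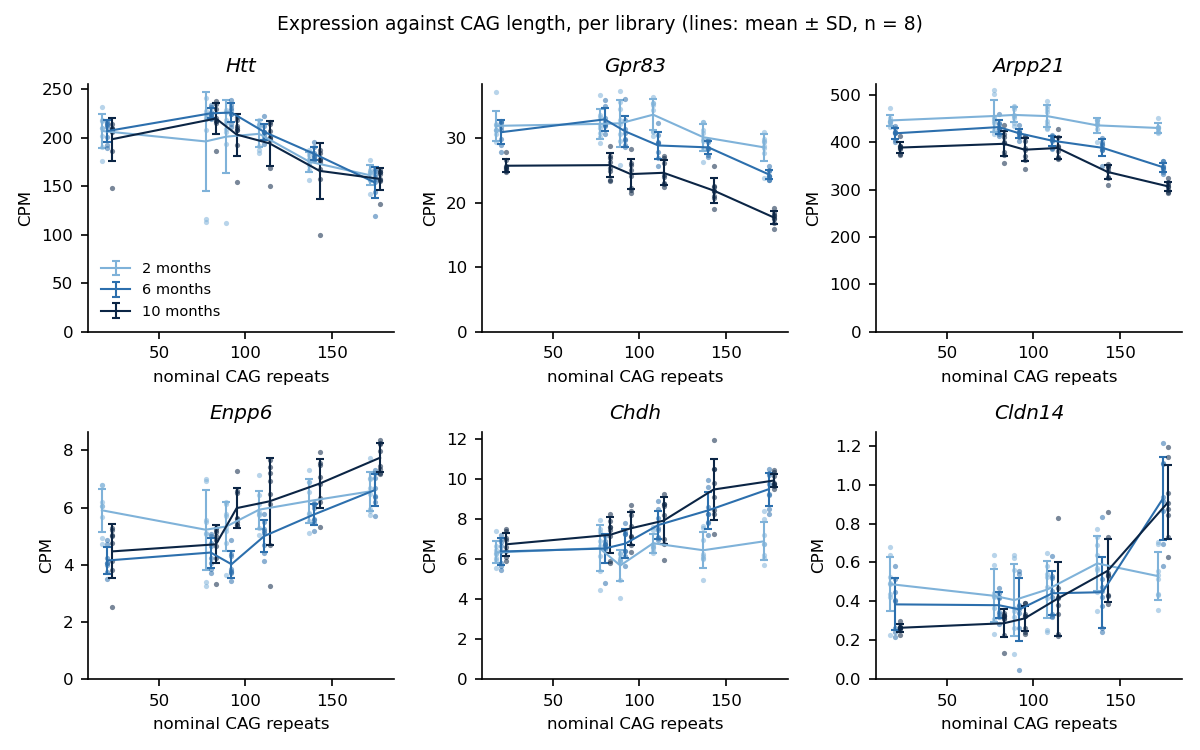
CPM of Htt, Gpr83, Arpp21, Enpp6, Chdh and Cldn14 (vertical axes) against nominal CAG length (horizontal axis). Points are libraries and bars the group mean ± SD (n = 8), so that Gpr83 at 10 months is seen to pass from 25.7 CPM in Q20 to 17.7 CPM in Q175.

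The slope along CAG length asks which cortical transcripts follow the length of the repeat, and at 10 months Cldn14, Chdh, Enpp6, Gpr83 and Arpp21 were among the genes with the smallest p. Cldn14, a tight-junction claudin (ENSMUSG00000047109, chromosome 16 from 93919031 to 94008837), rose from 0.264 ± 0.0193 CPM in Q20 to 0.91 ± 0.191 CPM in Q175 (SD, n = 8), a 2.40-fold change per 100 repeats (slope 1.26 ± 0.13, adjusted p = 2.7e-09). Chdh, which oxidises choline (ENSMUSG00000015970, chromosome 14 from 30009023 to 30040527), rose from 6.75 ± 0.588 to 9.95 ± 0.349 CPM (slope 0.40 ± 0.05, adjusted p = 1.7e-06). Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes (ENSMUSG00000038173, chromosome 8 from 46986887 to 47096762), rose from 4.47 ± 0.946 to 7.75 ± 0.51 CPM (slope 0.54 ± 0.08). Gpr83, a G protein-coupled receptor (ENSMUSG00000031932, chromosome 9 from 14860210 to 14870789), fell from 25.7 ± 1.02 to 17.7 ± 0.98 CPM (slope -0.33 ± 0.04, adjusted p = 4.9e-07). Arpp21, a cAMP-regulated phosphoprotein (ENSMUSG00000032503, chromosome 9 from 112065091 to 112235938), fell from 389 ± 12.1 to 307 ± 10.3 CPM (slope -0.23 ± 0.03, adjusted p = 1.7e-06).

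Among the other named genes of 10 months, the solute carrier Slc45a3 rose with a slope of 0.76 ± 0.10, the interleukin 12 receptor subunit Il12rb1 with 0.87 ± 0.12 and the paired-box transcription factor Pax2 3.47-fold per 100 repeats (adjusted p = 1.5e-05). The lipid transporter Abca8a rose by 0.30 ± 0.04, the growth factor receptor Met by 0.47 ± 0.07, the channel-like gene Tmc3 by 0.31 ± 0.05 and Polr2a, the largest subunit of RNA polymerase II, by 0.23 ± 0.03. The orphan receptor Gpr153 had a slope of -0.56 ± 0.08 (adjusted p = 3.1e-06), the fatty acid desaturase Fads1 -0.17 ± 0.02 (adjusted p = 1.8e-07) and carbonic anhydrase Car2 -0.20 ± 0.03. Mfge8, which links dying cells to phagocytes, had a slope of -0.29 ± 0.04, the AMPA receptor partner Gsg1l -0.28 ± 0.04, the kinase Hipk4 -0.36 ± 0.05, the microtubule-associated Map6d1 -0.18 ± 0.03 and the lipid phosphatase Plpp3 -0.18 ± 0.03. For each of these 20 genes, 8 of 8 Q175 libraries lay on the called side of the Q20 median. The genes were picked by p in these same libraries, so this is no separate support. In all, 998 of 17149 genes passed, 421 higher and 577 lower with CAG length. Without Q175, 8 genes passed, among them Cldn14, Slc45a3, Chdh, Il12rb1, Enpp6, Fads1 and Car2, while the slope of Pax2 was 0.06. Without the 9 libraries that correlated least with the others of their age, 1796 genes passed.

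Markers of astrocytes, of upper cortical layers and of cAMP and calcium signalling fell together at 10 months. Of 16 astrocyte markers 9 fell (11 fell and 1 rose when adjusted over the list alone), among them glutamine synthetase Glul (-0.21 ± 0.03), the bicarbonate transporter Slc4a4 (-0.17 ± 0.03), the aldolase Aldoc (-0.18 ± 0.03) and the gap junction gene Gja1 (-0.16 ± 0.03), with a camera adjusted p of 2.8e-11 and an adjusted p = 0.026 with an estimated correlation, which became 0.055 without the 9 libraries that correlated least. Of 12 upper-layer markers 5 fell (6 adjusted over the list alone), led by the endoplasmic reticulum protein gene Wfs1 (-0.45 ± 0.07), Lamp5 (-0.33 ± 0.06), Rasgrf2 (-0.20 ± 0.03) and Cux1 (-0.11 ± 0.03), with an adjusted p of 6.6e-07 and an adjusted p = 0.0075 with an estimated correlation. Of 30 genes of cAMP, calcium and opioid signalling 10 fell (13 adjusted over the list alone), among them the kinases Camk2a (-0.21 ± 0.03) and Camkk2 (-0.21 ± 0.03), with an adjusted p of 7.4e-11 and an adjusted p = 0.017 with an estimated correlation. Of 22 markers of striatal projection neurons, a neighbouring tissue, 5 fell (7 adjusted over the list alone), including proenkephalin Penk (-0.74 ± 0.12), the phosphatase inhibitor Ppp1r1b (-0.39 ± 0.07), the sodium channel subunit Scn4b (-0.30 ± 0.06) and Rasd2 (-0.21 ± 0.04), with an adjusted p of 2.2e-06 and an adjusted p = 0.32 with an estimated correlation. Penk, Ppp1r1b, Adcy5 and Pde10a belong to both the striatal and the signalling list, and Wfs1 also to the hippocampal list.

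Smaller parts of other lists passed at 10 months. Of 41 potassium channel genes 8 fell (12 adjusted over the list alone), led by the glial channel Kcnj10 (-0.19 ± 0.03) and Kcnh4 (-0.30 ± 0.06), with an adjusted p = 0.23 with an estimated correlation. Of 25 cholesterol synthesis genes 5 fell (10 adjusted over the list alone), including Hmgcs1 (-0.12 ± 0.03) and Fdft1 (-0.11 ± 0.03), with an adjusted p = 0.28 with an estimated correlation. Among receptors, 4 of 22 for glutamate fell (4 adjusted over the list alone, Grm3 by -0.17 ± 0.03), and 2 of 16 for GABA fell (3 adjusted over the list alone), Gabrd by -0.29 ± 0.04 and the transporter Slc6a11 by -0.11 ± 0.03. Of 22 interneuron markers Npy (-0.14 ± 0.04) and Dlx1 (-0.11 ± 0.03) fell (2 adjusted over the list alone), of 12 glutamatergic markers Camk2a fell (1 rose and 3 fell adjusted over the list alone), and of 16 clock genes Per3 (-0.18 ± 0.04) fell (4 adjusted over the list alone). Of 24 interferon-stimulated genes Ifit2 (0.14 ± 0.04), Irf7 (0.25 ± 0.07) and Psmb8 (0.18 ± 0.05) rose (4 adjusted over the list alone), and without Q175 the slope of Irf7 was -0.001. Of 14 developmental transcription factors Onecut2 (0.74 ± 0.12), Onecut1 (1.34 ± 0.29) and Shox2 (1.69 ± 0.45) rose (4 adjusted over the list alone). By camera with its preset correlation the interneuron (adjusted p = 0.004), potassium channel (1.3e-05), cholesterol (1.3e-05), GABA (0.03), clock (0.031) and interferon (0.0032) lists passed. None of these 6 passed with an estimated correlation, where the adjusted p = 0.23 for interneuron markers and 0.32 for the GABA, clock and interferon lists. The lists of glutamate receptors (adjusted p = 0.058), glutamatergic markers (0.073) and developmental factors (0.06) did not pass. Without the 9 libraries that correlated least the clock list had an adjusted p = 0.079 and the glutamate receptor list passed (adjusted p = 0.028, and 0.34 with an estimated correlation).

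In the remaining lists of 10 months few genes passed. Enpp6 was the 1 of 24 oligodendrocyte markers that rose (2 rose and 7 fell adjusted over the list alone), and the list's median slope of 0.016 and mean of 0.009 were positive while its test pointed down (adjusted p = 0.98). Serpina3n, a protease inhibitor of reactive astrocytes (0.24 ± 0.05), and S1pr3 (0.14 ± 0.03) rose and the complement gene C4a (-0.25 ± 0.08) fell among 19 gliosis genes, whose median of -0.066 and mean were negative while the test pointed up (adjusted p = 0.82). Psat1 of serine synthesis (0.12 ± 0.03) rose and the stress genes Ddit3 (-0.14 ± 0.04) and Sdf2l1 (-0.29 ± 0.09) fell among 24 stress response genes (adjusted p = 0.12). The receptor gene Eda2r (0.37 ± 0.11) rose and Ccng1 (-0.11 ± 0.03) fell among 17 p53 targets (adjusted p = 0.96). Single members passed among immediate early genes (Nptx2, -0.39 ± 0.11), heat shock genes (Hspa1b, -0.48 ± 0.13), hippocampal markers (Wfs1), thalamic markers (Pdp1, -0.28 ± 0.07) and beta protocadherins (Pcdhb9, 0.08 ± 0.03), with adjusted p = 0.55, 0.55, 0.55, 0.68 and 0.031 for the lists. The median of the thalamic list was 0.026 while its test pointed down, and the protocadherin list had an adjusted p = 0.32 with an estimated correlation. Adjusted over the list alone, 3 protocadherins rose, and the counts of the other 7 lists of this paragraph apart from the oligodendrocyte markers stayed as given. Nptx2 is also an upper-layer marker, and C4a, Hspa1b and Pcdhb9 have close relatives with which reads can be shared.

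No member passed at 10 months among the mismatch repair genes (median slope 0.059, adjusted p = 0.0042, and adjusted p = 0.20 with an estimated correlation) or the 13 mitochondrially encoded transcripts (median -0.061, adjusted p = 0.01, and adjusted p = 0.66 with an estimated correlation). The choroid plexus markers, also of a neighbouring tissue, had a median slope of -0.70 with no member called (adjusted p = 0.0024, and adjusted p = 0.53 with an estimated correlation). Nor did any member pass among markers of microglia (adjusted p = 0.96), endothelium (0.66), oligodendrocyte precursors (0.35), deep layers (0.79) and blood (0.22) or the nuclear genes of the respiratory chain (0.79). Adjusted over the list alone, 2 deep-layer markers rose and 2 fell, and 1 blood gene rose.

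**Figure D2:**
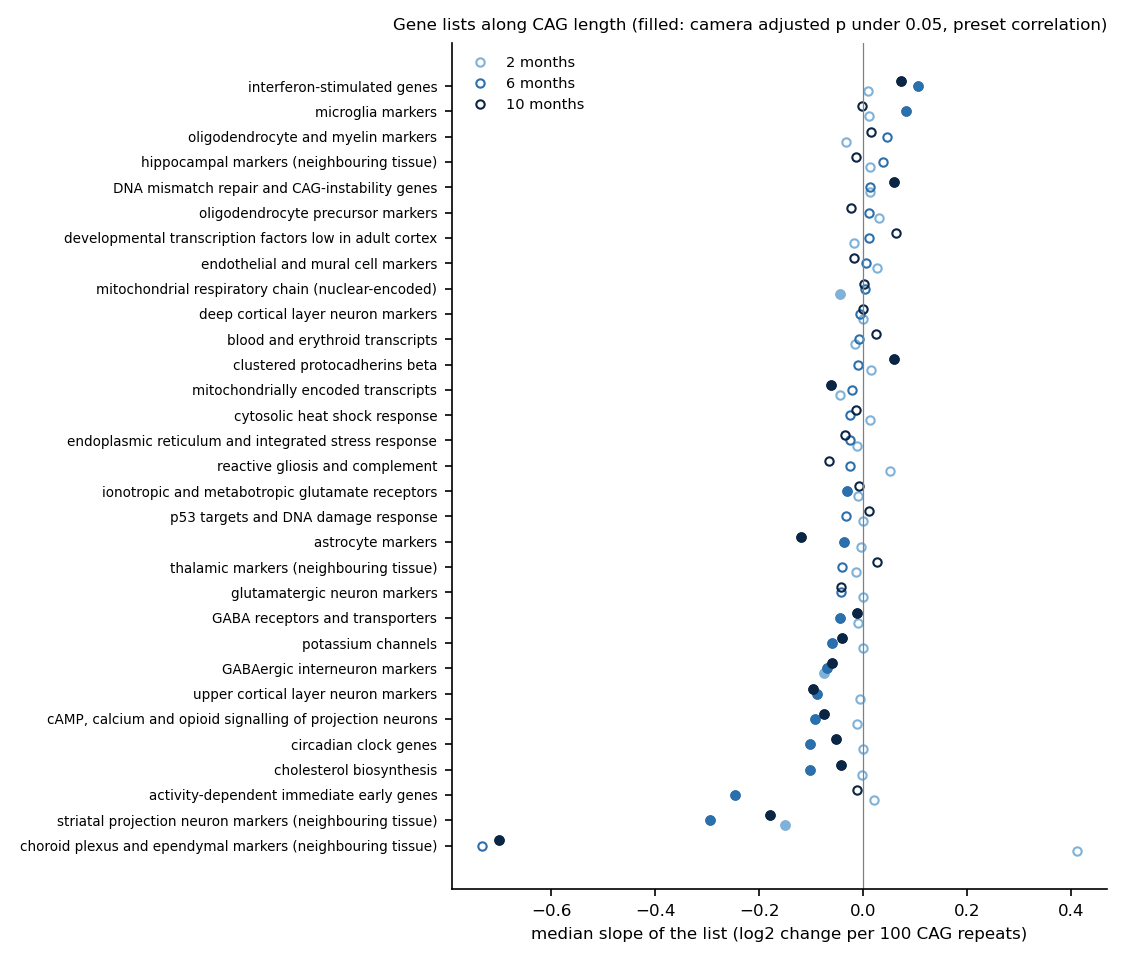
Median slope of each gene list (log2 per 100 CAG repeats, horizontal axis) at 2, 6 and 10 months, with 1 line per list and 1 marker per age, filled where camera with its preset correlation passed. The astrocyte list lies at -0.119 at 10 months and the microglia list at 0.083 at 6 months.

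At 6 months the slope again took in Enpp6, Chdh, Gpr153 and Arpp21, with a sodium channel subunit and an opioid precursor among the genes that fell. Enpp6 rose from 4.15 ± 0.456 CPM in Q20 to 6.61 ± 0.556 CPM in Q175 (SD, n = 8; slope 0.47 ± 0.05, adjusted p = 5.3e-08). Scn4b (ENSMUSG00000046480, chromosome 9 from 45138395 to 45154152) fell by 0.48 ± 0.05 per 100 repeats on the log2 scale (adjusted p = 5.9e-08) and Penk (ENSMUSG00000045573, chromosome 4 from 4133531 to 4138819) by 0.49 ± 0.06 (adjusted p = 4.2e-07). Gpr153 (ENSMUSG00000042804, chromosome 4 from 152274232 to 152285337) had a slope of -0.34 ± 0.04 (adjusted p = 1.7e-07), Arpp21 -0.18 ± 0.02 and Ptprv, a phosphatase relative annotated as a processed transcript, -0.83 ± 0.09. Abca8a rose by 0.31 ± 0.04, Chdh by 0.40 ± 0.05, Psat1 by 0.15 ± 0.02, the mitochondrial carrier Slc25a27 by 0.10 ± 0.01 and the lipid phosphatase Plpp2 by 0.40 ± 0.05. The collagen Col12a1 rose by 0.24 ± 0.03, the semaphorin receptor Plxnb3 by 0.24 ± 0.03, the tyrosine-degrading enzyme Fah by 0.16 ± 0.02 and anillin Anln by 0.32 ± 0.05. The cytokine Il33 had a slope of -0.22 ± 0.03, the chemokine receptor Ackr1 -0.18 ± 0.02, the GABA receptor subunit Gabrd -0.20 ± 0.03, the actin-capping gene Tmod1 -0.11 ± 0.01 and Pmepa1 -0.16 ± 0.02. For each of these 20 genes, 8 of 8 Q175 libraries lay on the called side of the Q20 median. The genes were picked by p in these same libraries, so this is no separate support. The leading numbers in the library names of the 6-month knock-ins form a separate block for each allele. Allele and block therefore cannot be told apart in the slope and allele comparisons of that age. In all, 1572 of 17546 genes passed, 713 higher and 859 lower. Without Q175, 367 passed, of which 141 were among the 1572, and each of the 20 genes still passed.

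Genes of cAMP and calcium signalling, interneuron and upper-layer markers and potassium channels fell and microglial markers rose at 6 months. Of 30 genes of cAMP, calcium and opioid signalling 18 fell (20 adjusted over the list alone), among them Penk, the G protein regulator Rgs4 (-0.20 ± 0.03) and the kinase genes Camk2b (-0.08 ± 0.01) and Camkk2 (-0.12 ± 0.02), with an adjusted p of 1.5e-17 and an adjusted p = 0.0068 with an estimated correlation. Of 20 microglia markers 11 rose (16 adjusted over the list alone), including the receptor Csf1r (0.10 ± 0.02), the protease Ctss (0.11 ± 0.02), Laptm5 (0.10 ± 0.02) and Itgam (0.12 ± 0.03), with an adjusted p of 9e-12 and an adjusted p = 0.033 with an estimated correlation. Of 22 interneuron markers 4 fell (8 adjusted over the list alone), namely Npy (-0.12 ± 0.02), Vip (-0.14 ± 0.03), Gad1 (-0.13 ± 0.03) and Dlx6 (-0.18 ± 0.06), with an adjusted p of 1.4e-05 and an adjusted p = 0.0043 with an estimated correlation. Of 12 upper-layer markers 6 fell (7 adjusted over the list alone), led by Lamp5 (-0.24 ± 0.03) and Wfs1 (-0.17 ± 0.03), with an adjusted p of 3.9e-05 and an adjusted p = 0.034 with an estimated correlation. Of 41 potassium channel genes 16 fell (1 rose and 19 fell adjusted over the list alone), among them Kcna1 (-0.15 ± 0.02), Kcnh5 (-0.27 ± 0.05) and Kcnip2 (-0.12 ± 0.02), with an adjusted p of 1e-10 and an adjusted p = 0.039 with an estimated correlation. Of 23 striatal markers 15 fell (18 adjusted over the list alone), including Scn4b, Penk, Cd4 (-0.78 ± 0.12) and Rasd2 (-0.19 ± 0.03), with a median slope of -0.294, an adjusted p of 2.3e-16 and an adjusted p = 0.078 with an estimated correlation.

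Of 26 immediate early genes 11 fell at 6 months (22 adjusted over the list alone), among them Egr2 (-0.81 ± 0.19), the cyclooxygenase gene Ptgs2 (-0.24 ± 0.06), the nuclear receptor Nr4a2 (-0.20 ± 0.05) and Nptx2 (-0.22 ± 0.06), with an adjusted p of 9e-12 and an adjusted p = 0.078 with an estimated correlation. Of 25 cholesterol synthesis genes 17 fell (19 adjusted over the list alone), including Insig1 (-0.27 ± 0.05), Stard4 (-0.16 ± 0.03), Idi1 (-0.17 ± 0.04) and Msmo1 (-0.14 ± 0.03), with an adjusted p of 6.6e-13 and an adjusted p = 0.057 with an estimated correlation. Of 16 clock genes 4 fell (10 adjusted over the list alone), led by Ciart (-0.36 ± 0.08) and Nr1d1 (-0.17 ± 0.04), with an adjusted p of 4.3e-06 and an adjusted p = 0.11 with an estimated correlation. Of 24 interferon-stimulated genes 3 rose (11 adjusted over the list alone), Irf7 (0.35 ± 0.07) and Xaf1 (0.20 ± 0.05) among them, with an adjusted p of 4.3e-06 and an adjusted p = 0.20 with an estimated correlation. Of 16 GABA genes 3 fell (10 adjusted over the list alone), Gabrd and Gabra4 (-0.06 ± 0.02) among them, with an adjusted p of 3.9e-05 and an adjusted p = 0.078 with an estimated correlation. Of 22 glutamate receptor genes 4 fell (5 adjusted over the list alone), led by Grm2 (-0.14 ± 0.04), with an adjusted p of 0.0088 and an adjusted p = 0.29 with an estimated correlation. Of 16 astrocyte markers S100b (0.15 ± 0.02) rose and 4 fell (1 rose and 5 fell adjusted over the list alone), including Glul (-0.11 ± 0.02), with an adjusted p of 0.015 and an adjusted p = 0.34 with an estimated correlation.

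The oligodendrocyte markers went both ways at 6 months, where 5 of 24 rose, led by Enpp6, and 6 fell, among them Tspan2 (-0.20 ± 0.03) and Fa2h (-0.14 ± 0.03), a fatty acid hydroxylase of myelin lipids, with 5 and 7 adjusted over the list alone (adjusted p = 0.90 for the list). Ntsr1 (0.11 ± 0.04) rose and Pcp4 (-0.15 ± 0.03), Nr4a2 and Cplx3 (-0.14 ± 0.04) fell among 16 deep-layer markers (adjusted p = 0.28), and Sv2b (-0.10 ± 0.03) and Camk2a (-0.09 ± 0.03) fell among 12 glutamatergic markers (adjusted p = 0.09). Without Q175 the slope of Camk2a was 0.018. Psat1 and Phgdh of serine synthesis (0.08 ± 0.02) rose and 4 stress response genes fell, Ddit3 (-0.09 ± 0.03) and Atf4 (-0.07 ± 0.02) among them (adjusted p = 0.45). Eda2r (0.38 ± 0.11) rose and 4 other p53 targets fell, including Cdkn1a (-0.26 ± 0.09), with an adjusted p = 0.067 for the list. The heat shock genes Hsp90aa1 (-0.07 ± 0.02) and Hspa4l (-0.08 ± 0.02) fell (adjusted p = 0.067), as did the thalamic markers Pdp1 (-0.23 ± 0.05) and Rora (-0.07 ± 0.02; adjusted p = 0.28). Onecut2 (0.28 ± 0.07; adjusted p = 0.46 for its list), the precursor marker Neu4 (0.13 ± 0.03; 0.22) and Serpina3n (0.18 ± 0.04; 0.95) were the members of their lists that rose. Adjusted over the list alone, the counts that changed were 3 for glutamatergic markers, 5 for falling stress genes, 3 for heat shock genes, 1 rising thalamic marker and 2 rising and 1 falling gliosis genes.

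The choroid plexus markers had a median slope of -0.734 at 6 months, with no member called (9 fell adjusted over the list alone, adjusted p = 0.067), and Ttr, the transthyretin gene, at -1.81 ± 0.61. No member passed among endothelial markers (adjusted p = 0.84), blood genes (0.61), mitochondrially encoded transcripts (0.14), respiratory chain genes (0.43), beta protocadherins (0.71) and mismatch repair genes (0.40), and Wfs1 was the hippocampal marker that fell (1.0). The medians and tests pointed opposite ways for the hippocampal (0.039, down), endothelial (0.006, down) and gliosis (-0.026, up) lists. Liver transcripts, a list added after the values were seen, had positive slopes for 33 of 33 genes at 6 months with no gene called and a median of 1.615. The unadjusted camera p was 2.2e-04, and 0.45 with an estimated correlation.

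At 2 months Gpr153 was the 1 gene of 17115 that passed along CAG length, with a slope of -0.16 ± 0.03 (0.895-fold per 100 repeats, adjusted p = 0.0029). Without Q175 the slope of Gpr153 was -0.17 and no longer passed. Without the filter on low counts 69 genes passed at 2 months, 59 higher and 10 lower, with Gpr153 among them. No member of any list passed over all genes, and 597 genes had an unadjusted p under 0.05. The interneuron markers had negative slopes for 19 of 22 genes (5 fell adjusted over the list alone), with Gad1 at -0.14 ± 0.03 and Calb2 at -0.44 ± 0.11, an adjusted p of 2.5e-08 and an adjusted p = 0.00028 with an estimated correlation. Calb2 is also a thalamic marker, and 2 genes of that list fell adjusted over the list alone (adjusted p = 0.12 for the list). The striatal markers had negative slopes for 23 of 23 genes (1 fell adjusted over the list alone), Penk at -0.31 ± 0.10, with an adjusted p of 3.5e-14 and an adjusted p = 0.57 with an estimated correlation. The respiratory chain genes had negative slopes for 41 of 42 genes with a median of -0.044, an adjusted p of 6.2e-05 and an adjusted p = 0.86 with an estimated correlation. Serpina3n, at -0.14 ± 0.04, was the 1 gliosis gene that fell adjusted over the list alone (adjusted p = 0.20 for the list). The other 28 tested lists did not pass at 2 months. Without the 9 libraries that correlated least the respiratory chain list did not pass (adjusted p = 0.10), while the lists of microglia (upwards, adjusted p = 1e-04), glutamate receptors (downwards, 0.009), GABA genes (downwards, 0.02) and cAMP and calcium signalling (downwards, 0.022) did. With an estimated correlation none of these 4 passed there (adjusted p = 0.39, 0.37, 0.39 and 0.80). In the astrocyte, potassium channel and p53 lists mean, median and test differed in sign. The liver list added after the values were seen had a median of 0.288 over 9 genes, with none called (1 rose adjusted over the list alone). Its unadjusted camera p was 0.0044, and 0.13 with an estimated correlation.

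Whether the genes that followed CAG length at 6 months also did so at 10 months was asked over the 17028 genes tested at both ages. Enpp6, Chdh and Abca8a rose and Gpr153, Arpp21 and Penk fell at both. In all, 138 genes rose at both ages, where 17.5 would be shared by independent lists (Fisher's exact test, p = 2.2e-87), and 273 fell at both against 28.9 (p = 3.9e-209). No gene was called in opposite directions. Across genes, which are not independent replicates, the slopes had a Pearson r of 0.394 and a Spearman rho of 0.361. Between 2 and 10 months the Pearson r was 0.053 across genes.

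**Figure D3:**
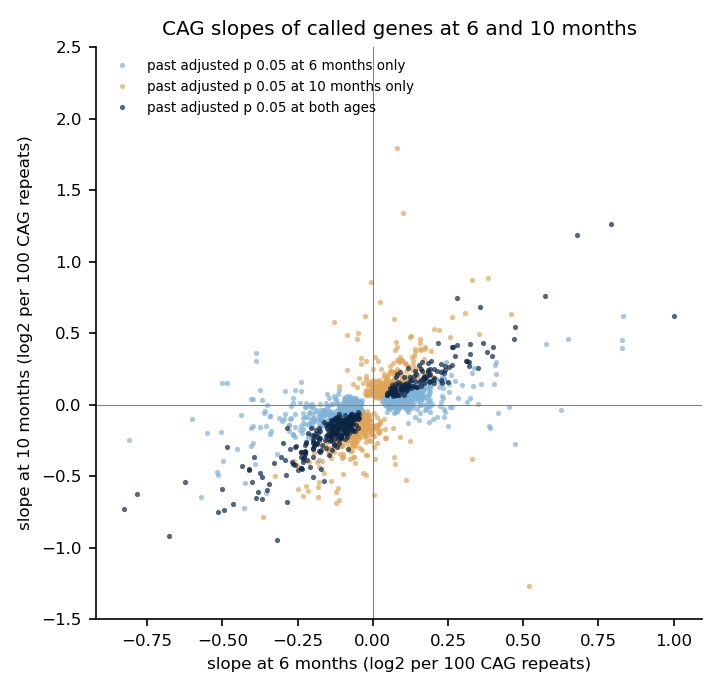
Slope per 100 CAG repeats at 10 months (log2, vertical axis) against that at 6 months (log2, horizontal axis), 1 point per gene called at either age, coloured by the age at which it passed. The 411 genes called at both ages had the same sign at both.

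Whether the slopes themselves changed with age was tested as a difference of slopes over the knock-in libraries of all ages. Between 2 and 10 months the slope rose for Serpina3n by 0.38 ± 0.06 (adjusted p = 5.1e-05), for the transcription factor Onecut2 by 0.76 ± 0.13 (adjusted p = 6.4e-05), for the Polycomb gene Cbx8 by 0.34 ± 0.06, and for Met by 0.44 ± 0.08. It fell for the polo-like kinase Plk5 (difference -0.88 ± 0.14, adjusted p = 3.6e-05), Wfs1 (-0.43 ± 0.07), Hipk4 (-0.36 ± 0.06) and Plpp3 (-0.19 ± 0.03). The slope of Plk5 was -0.05 at 2 months, -0.32 at 6 months and -0.94 at 10 months, and that of Onecut2 was -0.02, 0.28 and 0.74. In all, 397 genes differed, 135 upwards and 262 downwards, and 784 without the 9 libraries that correlated least with the others. Between 6 and 10 months 2 genes differed, Pax2 (1.65 ± 0.31, adjusted p = 0.0057) and Mfge8 (-0.24 ± 0.05, adjusted p = 0.031). DESeq2 called 16 for that pair of ages, without Pax2 (1.58) among them, and without the 9 libraries 106 genes differed. Mfge8 did not pass without the filter on low counts (adjusted p = 0.0506) or without the sex term (0.0507). The 6-month knock-in libraries differ in the series of their names from those of 10 months, so that age and library series cannot be told apart for this pair.

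Each longer allele was also set against Q20 of the same age, to show at which repeat length differences appeared. In Q175 at 10 months Onecut2 was 2.49-fold higher (log2 1.32 ± 0.11, adjusted p = 1.5e-12), Cldn14 3.37-fold (1.75 ± 0.20) and Pax2 5.95-fold (2.57 ± 0.31), with Cbx8 (0.54 ± 0.07) and the collapsin response gene Dpysl3 (0.34 ± 0.04) also higher. Gpr153 was lower than in Q20 (log2 -0.86 ± 0.07, adjusted p = 2.8e-13), Plk5 at 0.305 (-1.71 ± 0.16), and Hipk4 (-0.62 ± 0.05), Gpr83 (-0.54 ± 0.05) and Gabrd (-0.49 ± 0.05) were also lower. In Q175 at 10 months 1310 of 17219 genes passed, 495 higher and 815 lower. Q140 at 10 months differed in 22 genes, including Slc45a3 (0.82 ± 0.15), Chdh (0.48 ± 0.09), Arpp21 (-0.21 ± 0.04, adjusted p = 0.0085) and Fads1 (-0.15 ± 0.03). DESeq2 called 42 genes for Q140, 36 passed without the libraries that correlated least, and 7 did with only the 2 groups compared, 6 of them shared. Fads1 in Q140 did not pass with only the 2 groups compared (-0.15, adjusted p = 0.197) or with wild type as the reference (-0.11, adjusted p = 0.0656). In Q111 at 10 months Car2 (-0.22 ± 0.04), Fads1 (-0.15 ± 0.03) and Il33 (-0.30 ± 0.06) were lower and 6030443J06Rik (1.20 ± 0.24) higher, and no other gene passed. In Q80 the neuronal genes Nptx2 (0.55 ± 0.10) and Ptgs2 (0.50 ± 0.09), with Pknox1 (0.26 ± 0.05) and Gmeb2 (0.20 ± 0.04), were higher. Il33, 6030443J06Rik, Pknox1 and Gmeb2 were named after their values were seen. In Q92 edgeR called 0 genes, with 893 at an unadjusted p under 0.05 and 0 by DESeq2. With only the 2 groups compared both counts, for Q80 and Q111, were 0. The differences of Nptx2 (0.55), Ptgs2 (0.49), Car2 (-0.22) and Fads1 (-0.15) stayed about as large there, and their adjusted p were 0.224, 0.125, 0.187 and 0.468. Fads1 in Q111 also did not pass without the filter on low counts (adjusted p = 0.0794), without the sex term (0.0529) or without the 9 libraries (0.0644), and with wild type as the reference neither Car2 (-0.17) nor Fads1 (-0.11) in Q111 passed.

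**Figure D4:**
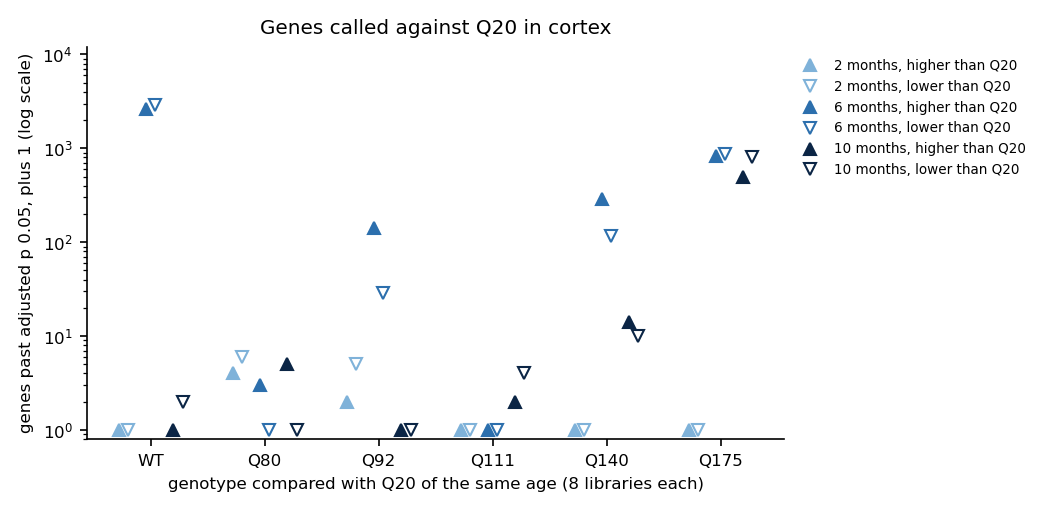
Number of genes called higher (filled) and lower (open) than in Q20, plus 1 (vertical axis, log scale), for each allele and wild type at 2, 6 and 10 months (n = 8 per group). Q175 has 829 higher and 862 lower genes at 6 months, and wild type 2634 and 2878.

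At 6 months Enpp6 was 1.59-fold higher in Q175 (log2 0.67 ± 0.07, adjusted p = 4.3e-09), and Psat1 (0.23 ± 0.03), the mitochondrial gene Echdc2 (0.40 ± 0.05), the presynaptic gene Tprgl (0.18 ± 0.02) and Chdh (0.57 ± 0.07) were higher too. Gpr153 was at 0.669 of its Q20 level (log2 -0.58 ± 0.05, adjusted p = 2.7e-12), and Htt, Plk5 (-0.59 ± 0.06), Arpp21 (-0.27 ± 0.03) and Gabrd (-0.32 ± 0.03) were lower. In Q175 at 6 months 1691 of 17611 genes passed, 829 higher and 862 lower, and 995 did with only the 2 groups compared, 944 of them shared. Q140 differed in 404 genes and Q92 in 170, and the smallest p among the higher genes went to liver genes. The urea cycle enzyme Cps1 was 11.5-fold higher in Q140 (3.53 ± 0.35) and 9.23-fold higher in Q92 (3.21 ± 0.35), and the bile salt pump Abcb11 was 23.0-fold (4.52 ± 0.47) and 18.7-fold (4.23 ± 0.48) higher. Albumin, Alb, lay between 15.1 and 358 CPM in these 16 libraries and at most at 5.31 CPM in the other 32 knock-in libraries of that age, and 33 liver genes were among the higher genes of each allele. Apart from those, the actin gene Actr3b (-0.19 ± 0.03, adjusted p = 7.8e-05) and tubulin Tuba8 (-0.32 ± 0.06) were lower in Q140, and the splicing factor Snrnp35 (-0.22 ± 0.05) and Pigyl (-0.22 ± 0.05) in Q92. With wild type as the reference, which at 6 months is of another library series, Tuba8 in Q140 was at -0.03 (adjusted p = 0.74). Pigyl in Q92 was then at 0.12 (adjusted p = 0.0589). With the liver level as a covariate, added after the values were seen and running along with these alleles, neither Q92 nor Q140 had a called gene. The differences were then -0.12 for Actr3b, -0.24 for Tuba8, -0.18 for Snrnp35 and -0.31 for Pigyl, so that the part of liver RNA in these genes stays open. In Q80 Cdr1 (0.30 ± 0.06) and the dynein regulator Drc1 (0.26 ± 0.05) were higher. With only the 2 groups compared Drc1 in Q80 (0.26, adjusted p = 0.316) and Snrnp35 in Q92 (-0.21, adjusted p = 0.108) did not pass. In Q111 edgeR called 0 genes, with 1368 at an unadjusted p under 0.05 and 9 by DESeq2.

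**Figure D5:**
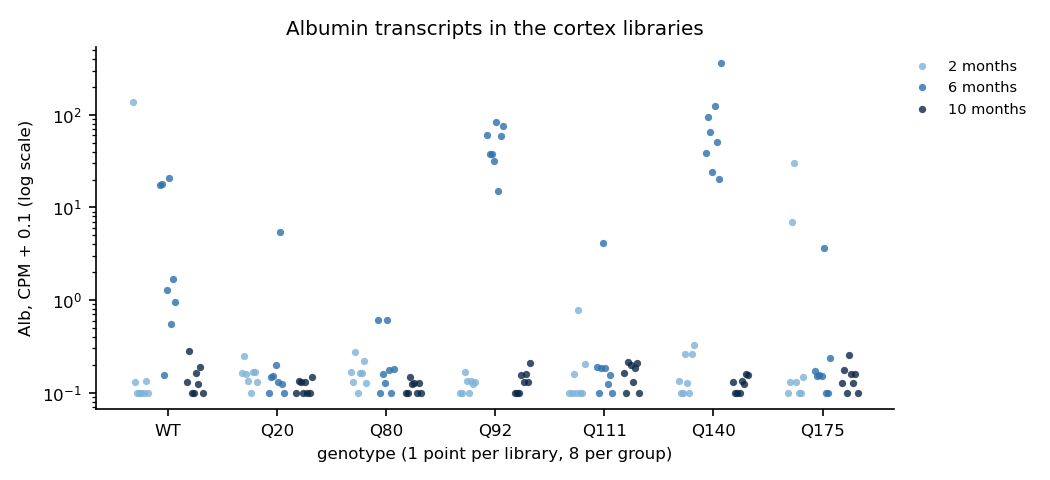
Albumin (Alb) transcripts (CPM + 0.1, vertical axis, log scale) in each library, by genotype and age (horizontal axis), 1 point per library. The 16 Q92 and Q140 libraries of 6 months lie between 15.1 and 358 CPM.

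At 2 months few genes passed against Q20, although 3249 of 17194 genes for Q80 and 941 for Q92 had an unadjusted p under 0.05. In Q80 Galnt11, a sugar transferase of O-glycosylation (0.23 ± 0.04, adjusted p = 0.013), was higher, and Prune2 (-0.25 ± 0.04, adjusted p = 0.0038) and the proteoglycan gene Nyx (-0.82 ± 0.15) were lower, among 8 genes in all. Leaving out Q80 male 1 of that age, which had no Y-linked signal, gave 17 genes, and DESeq2 called 73. In Q92 Drc1 (0.28 ± 0.05) was higher and the matrix gene Postn (-0.64 ± 0.13), Nyx (-0.72 ± 0.14), the meiotic cohesin gene Rec8 (-0.65 ± 0.13) and 1700012B09Rik were lower, the last 2 named after their values were seen. Without the 9 libraries that correlated least, of which Q80 female 3, Q80 male 5 and Q92 male 3 are of this age, Galnt11 (0.21, adjusted p = 0.0941) in Q80 and Nyx (-0.66, adjusted p = 0.0561) in Q92 no longer passed. Galnt11 did not pass with the replicate block either (0.22, adjusted p = 0.0525). With only the 2 groups compared Galnt11 (0.23) and Prune2 (-0.25) in Q80 and Drc1 (0.28), Postn (-0.64) and Nyx (-0.72) in Q92 had unaltered differences and did not pass. With wild type as the reference Prune2 (-0.17) and Nyx (-0.42) in Q80 and Drc1 (0.25), Postn (-0.37) and Nyx (-0.33) in Q92 did not pass. With edgeR 0 genes passed in Q111, Q140 and Q175, with 447, 398 and 567 at an unadjusted p under 0.05 and 3, 4 and 3 by DESeq2.

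Wild type against Q20 asks whether the knocked-in allele with a short repeat differs from the untouched gene. At 10 months Abhd1, an abhydrolase gene (ENSMUSG00000006638, chromosome 5 from 30950066 to 30955091), was at 0.397 of its Q20 level in WT (log2 -1.33 ± 0.19, adjusted p = 5.5e-05), and it was the 1 gene called. At 2 months edgeR called 0 genes, with 530 at an unadjusted p under 0.05 and 1 by DESeq2. At 6 months 5512 of 17611 genes passed, 2634 higher and 2878 lower in WT. The ubiquitin and ribosomal fusion gene Rps27a (0.69 ± 0.04), Lrrc17 (3.37 ± 0.21) and the mitochondrial transcripts mt-Nd3 (0.81 ± 0.05) and mt-Nd4l (0.80 ± 0.05) were higher. The ribosomal gene Rps16 (-1.49 ± 0.08), the helicase Ddx54 (-0.40 ± 0.03), the co-chaperone Hspbp1 (-0.46 ± 0.04), dynactin Dctn1 (-0.30 ± 0.02) and Rnf187 (-0.28 ± 0.02) were lower, and reads of Rps27a and Rps16 can be shared with their pseudogenes. Of the 5512 genes, 1 was also called at 2 or 10 months. All 6-month knock-in libraries carry names of 1 series, while the 6-month wild types carry names like those of all libraries of 2 and 10 months, so that genotype and library series cannot be told apart at that age.

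Whether the slope along CAG length differed between females and males was tested at 6 and 10 months. At 6 months edgeR called 0 genes, with 1190 at an unadjusted p under 0.05 and 2 by DESeq2. At 10 months edgeR called 0 genes, with 558 at an unadjusted p under 0.05 and 0 by DESeq2. In simulated data, a sex difference in slope of 0.4 was found for 58.2% of the changed genes at 10 months and a difference of 0.8 for 81.8%.

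Q20 mice of 10 months were set against those of 2 months to show differences between ages without an expanded repeat. The library names of these 2 ages share a format but have separate runs of leading numbers. Age and run therefore cannot be told apart. Spag6, of the ciliary axoneme, rose 2.28-fold (log2 1.19 ± 0.08, adjusted p = 7.7e-26, n = 8 per age), Abca8a 1.70-fold (0.76 ± 0.07), the Wnt modulator Dkk3 by 0.50 ± 0.04 and Il33 by 0.54 ± 0.05. Pcdhb9 (0.52 ± 0.05), Gatm of creatine synthesis (0.45 ± 0.05), Plxdc1 (0.51 ± 0.05) and the potassium channel Kcnc2 (0.27 ± 0.03) also rose. Rnf122, a ubiquitin ligase, was at 0.496 of its 2-month level (log2 -1.01 ± 0.09, adjusted p = 5.6e-19) and the phosphatase Ptpro at 0.365 (-1.45 ± 0.14). Dpysl3 (-0.49 ± 0.04), the AMPA receptor partner Cacng4 (-0.59 ± 0.05), Marcksl1 (-0.97 ± 0.09), Rimklb (-0.38 ± 0.04), the G protein subunit Gng7 (-0.79 ± 0.08) and the adenylyl cyclase Adcy5 (-0.58 ± 0.06) fell. In all, 3234 of 17981 genes passed, 1599 higher and 1635 lower at 10 months.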

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

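The tests of single libraries and of slope differences were fixed beforehand, and the set of 9 libraries that correlated least was chosen after the values were seen. In groups of 8 libraries, a library was singled out when its gap to the nearest other exceeded Dixon's critical share of the group's range, and this was met in 25 of 273 groups tested, while chance alone gives about 1 in 20.

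Htt was low in 1 library of 6 groups. It stood at 112 CPM in Q92 male 3 of 2 months (the others 194 to 228), 148 in Q20 male 2 of 10 months (186 to 214), 186 in Q80 female 4 of 10 months (215 to 238), 154 in Q92 male 2 of 10 months (193 to 222), 99.4 in Q140 female 3 of 10 months (157 to 187) and 131 in Q175 male 2 of 10 months (156 to 167). Q92 male 3 of 2 months, Q20 male 2, Q92 male 2 and Q140 female 3 of 10 months are among the 9 libraries that correlated least with the others of their age. So is Q80 male 4 of 10 months. In those 9 Xkr4 had a median of 5.43 CPM against 15.6 CPM in the other 159, and mitochondrial transcripts took a median of 13.1% of counts against 11%, but Q80 male 4 of 10 months differed from the rest of the 9, with Xkr4 at 13.4 CPM and 7.44% mitochondrial transcripts. Cldn14 was high in WT female 3 of 6 months (0.564 CPM, the others 0.21 to 0.367), Q140 male 4 of 6 months (0.832, 0.24 to 0.514) and Q111 female 2 of 10 months (0.83, 0.223 to 0.47). Slc45a3 stood at 1.29 CPM in Q80 male 4 of 10 months (0.475 to 0.843) and Gpr153 at 31.5 CPM in the same library (20.9 to 25.5). Chdh stood at 4.83 CPM in Q80 male 1 of 6 months (6.49 to 7.19) and Abca8a at 10.4 CPM in Q20 male 1 of 6 months (12.3 to 13.1). Gpr83 was high in Q20 female 2 of 2 months (37.2 CPM, 29.5 to 32.1) and low in Q175 male 1 of 2 months (23.9 CPM, 27.7 to 30.9). Arpp21 stood at 401 CPM in Q140 female 3 of 2 months (428 to 448), 451.7 in Q175 female 2 of 2 months (421 to 432), 349 in Q140 male 4 of 6 months (384 to 410) and 414 in Q20 female 3 of 10 months (374 to 393). Ptprv stood at 7.85 CPM in Q80 female 3 of 6 months (4.33 to 5.98). Scn4b was high in Q20 female 2 of 2 months (141 CPM, 105 to 115), Q80 male 3 of 2 months (137, 111 to 121) and Q175 female 3 of 10 months (97.9, 69.3 to 82.8). The total of estimated counts, in units of mega-counts, was 44.5 in WT female 1 of 2 months (29.3 to 34.8) and 42.5 in WT male 2 of 10 months (31.4 to 35.2).

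The slope along CAG length differed between ages by the test of the difference itself, between 2 and 10 months for 397 genes and between 6 and 10 months for 2. Between 2 and 10 months the difference was 0.38 for Serpina3n, 0.76 for Onecut2, 0.34 for Cbx8 and 0.44 for Met. It was -0.88 for Plk5, -0.43 for Wfs1, -0.36 for Hipk4 and -0.19 for Plpp3. Between 6 and 10 months it was 1.65 for Pax2, whose slope without Q175 was 0.06 at 10 months, and -0.24 for Mfge8, and the 6-month knock-ins are by their names in another library series than those of 10 months. Of 33 splits, all but the real one shuffled the knock-in alleles among the libraries within each age. The real one alone gave as many as 397 genes and the highest other gave 5. Such splits take away the slope at every age, so that they do not by themselves test whether slopes differ between ages. For 6 against 10 months 5 of 33 splits gave as many as 2 genes and the highest other gave 140, so that chance cannot be excluded, and a split with so many calls points to a structure of the samples.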

How the results depend on the processing

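The fits without the 9 libraries that correlated least, without Q80 male 1 of 2 months and with the liver covariate were chosen after the results were seen. Of 402 summary results, 30 are those reported, and under the alternatives 302 stayed within 1.5 times the reported count and 70 moved further. The 302 include the 48 fits of each slope that left out 1 library, none of which moved. Counts of 0 that stayed at 0 are also among them, so the tally overstates how stable the results are. Of the single genes, 141 values passed newly, 239 no longer passed and 5 of called genes turned direction, and 117 of the 239 were lost without Q175. The other 5344 values were counted as unchanged. That count also takes in any gene not called in the reported fit that turned direction. The counts of the slopes at 6 and 10 months stayed within 1.5 times under DESeq2 (1869 and 1147), the rank of the allele (1903 and 1300) and limma on log2 FPKM (1667 and 1219 with a pseudocount of 0.1). The limma fits shifted the share of called genes that were higher, to 67.4% at 6 months and 62.3% at 10 months from 45.4% and 42.2%. Among 200 genes changed in simulated data, those with a change of 0.2 were found in 71.6% for the slope at 10 months, 44.8% for the difference of 2 and 10 months and 17.9% for the difference between sexes, so that small differences of the last kind can stay unseen at this depth and number of libraries. The cause of the shifts listed here was not tested.

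With DESeq2 as the test the counts were 73 for Q80, 14 for Q92, 3 for Q111, 4 for Q140, 3 for Q175 and 1 for WT at 2 months, 9 for Q111 at 6 months, 12 for Q80, 7 for Q111 and 42 for Q140 at 10 months, 2 for the sex difference at 6 months and 16 for the slope difference of 6 and 10 months. With its size factors in edgeR Q111 at 2 months had 1 gene. Without a filter on low counts the 2-month slope had 69 genes and the difference of 6 and 10 months had 1. Without the sex term the 2-month slope had 2, Q92 at 2 months 3, Q111 at 2 months 1 and the difference of 6 and 10 months 1. With the replicate block Q92 at 2 months had 9, Q140 at 6 months 615, of which 403 were shared, the difference of 6 and 10 months 4 and the slope at 6 months 2162. Libraries of the same replicate number had a mean correlation of 0.01, 0.061 and 0 at 2, 6 and 10 months. At these ages 46, 58 and 36 such pairs lay over 0.1, the highest at 0.4, 0.308 and 0.38. Pairs of other numbers had means of -0.001, -0.02 and 0. The means differed most at 6 months, so that a weak structure along the numbers stays open at that age. With only the 2 groups compared Q80, Q92, Q111, Q140 and Q175 at 2 months had 2, 0, 2, 2 and 5 genes, Q80, Q92 and Q175 at 6 months 1, 98 and 995, and Q80, Q92, Q111, Q140 and WT at 10 months 0, 1, 0, 7 and 2. With wild type as the reference Q92 at 2 months had 0, Q80, Q92, Q111, Q140 and Q175 at 6 months 5747, 5109, 6294, 6014 and 7446, and Q80, Q92, Q111 and Q140 at 10 months 10, 3, 1 and 61. Pigyl in Q92 at 6 months then turned to 0.122. With the wild types added to the slope, 2 genes passed at 2 months and 5249 at 6 months.

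Without Q175 the slopes had 0, 367 and 8 genes at 2, 6 and 10 months, and those of Camk2a (0.018) and Slc1a2 (0.007) at 6 months and of Irf7 (-0.001) and Kcnip2 (0.004) at 10 months turned direction. Leaving out each library in turn gave 1 gene at 2 months, 1151 to 1888 at 6 months and 715 to 1415 at 10 months. Without the 9 libraries the slopes at 2 and 10 months had 2 and 1796 genes, the differences of 10 months from 2 and 6 months 784 and 106, Q92, Q111, Q140, Q175 and WT at 2 months 3, 3, 4, 3 and 1, Q80 and Q140 at 10 months 13 and 36, and 6 lists passed at 2 months. Leaving out the single replicate Q80 male 1 gave 17 genes for Q80 at 2 months. With the liver covariate, which runs along with both alleles, Q92 and Q140 at 6 months had 0 and 0 genes, as Cps1 in Q140 passed from 3.53 to 0.35 and Abcb11 from 4.52 to 1.55. Genes outside the liver list also lost their calls there. Their differences went in Q140 for Htt from -0.17 to -0.19, Tuba8 from -0.32 to -0.24 and Actr3b from -0.19 to -0.12, and in Q92 for Pigyl from -0.22 to -0.31 and Snrnp35 from -0.22 to -0.18, so that the part of liver RNA in them stays open. Of the gene lists 3, 13 and 14 passed camera with the preset correlation at 2, 6 and 10 months, against 1, 5 and 3 with an estimated correlation and 1, 14 and 9 with fry.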

Other observations

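The tests of the liver transcripts, of the wild types at 6 months and of the genes near Htt were chosen after the results were seen, and the splits of the libraries were fixed beforehand.

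Several genes called for single alleles lie close to Htt. Drc1, a regulator of ciliary dynein on the same chromosome, was higher than in Q20 by 0.28 ± 0.05 in Q92 at 2 months, 0.26 ± 0.05 in Q80 at 6 months and 0.24 ± 0.05 in Q140 at 6 months (n = 8 per group), of which those in Q80 and Q92 did not pass with only the 2 groups compared. Galnt11 was higher by 0.23 ± 0.04 in Q80 at 2 months and 0.20 ± 0.04 in Q140 at 6 months, and Abhd1 in wild type differed from Q20 by -0.89, -1.22 and -1.33 at 2, 6 and 10 months. Galnt11 in Q80 did not pass with only the 2 groups compared or without the 9 libraries that correlated least.

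Within 20 Mb of Htt lay 6 of the 40 genes called for the alleles other than Q175 or for wild type at 2 and 10 months, against 0.58 for independent lists (Fisher's exact test, p = 2.2e-05). Sequence variants of the donor chromosome linked to the knock-in are a candidate explanation for these positions, and variants were not read from sequence. CAG length acting on neighbours of Htt was asked of a wider set, the genes of that window other than Htt called for an allele but Q175 at any age, mostly Q140 at 6 months, or for wild type at 2 or 10 months. It stays open, because 2 of the 15 tested passed along CAG length at 10 months, against 998 of 17149 of all genes (one-sided Fisher's exact test for a higher share, p = 0.22, and for a lower one, p = 0.95).

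Liver transcripts in the 16 Q92 and Q140 libraries of 6 months rose and fell together, with a median Pearson r of 0.954 with Alb over the other liver genes above 1 CPM. RNA from liver in these libraries may account for them, in which Alb had a median of 48.1 CPM in Q92 and 57.7 CPM in Q140. A rise with CAG length is argued against by the highest Alb of 3.98 CPM in the 16 Q111 and Q175 libraries of that age, and an effect of both alleles at each age by the highest Alb of 0.225 CPM in their 32 libraries of 2 and 10 months. Alb also reached 138 CPM in 1 wild-type library of 2 months, 30 and 6.92 CPM in 2 Q175 libraries of 2 months and 20.8 CPM among the wild types of 6 months, and 1 liver gene is also on a hippocampal list. How the transcripts came into the libraries was not tested.

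Wild type and Q20 differed in 5512 genes at 6 months. A genotype difference present at each age is argued against, since these genes, taken in their 6-month direction, had a median log2 difference of -0.021 at 2 months (quartiles -0.059 and 0.020) and -0.022 at 10 months (quartiles -0.046 and 0.002), against a median size of 0.155 at 6 months. Q20 libraries that stand apart from the other alleles are argued against as well, since Q80 differed from Q20 in 2 genes. Every allele differed from wild type in at least 5109 genes at that age, and for the 5512 genes the wild types of 6 months lay a median of 0.042 (log2) from the mean of their own 2-month and 10-month levels, against 0.181 for Q20 and up to 0.196 for the other alleles. The library series and the genotype cannot be told apart, because by their names all 6-month knock-ins are in 1 series and the 6-month wild types in that of all libraries of 2 and 10 months, and a difference of wild type from every knock-in at 6 months alone stays open, untested.

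The libraries were also split at random into groups of the same sizes. For the slope at 6 months 1 of 100 splits, the real one, gave as many as 1572 genes (highest other 1), and at 10 months 1 of 100 gave as many as 998 (highest other 484), so that chance can be excluded for both. At 6 months each knock-in allele has its own block of leading numbers in the library names. Random splits cannot tell allele from such a block, in the slope or in the allele comparisons of that age. For the slope at 2 months 10 of 100 splits gave as many as the 1 gene found, the highest other gave 3576, and chance cannot be excluded. That many calls points to a structure of the samples at 2 months. In the comparisons with Q20, 1 of 25 splits, the real one, reached the count for Q80 (8, highest other 2) and Q92 (5, highest other 0) at 2 months. The same held for Q92 (170, highest other 0), Q140 (404, 16), Q175 (1691, 396) and WT (5512, 2897) at 6 months. It also held for Q140 (22, 1), Q175 (1310, 101) and WT (1, 0) at 10 months. This is the lowest share that 25 splits allow, without adjustment over the comparisons, so by itself it does not exclude chance. For Q80 at 6 months 2 of 25 splits reached 2 genes (highest other 30). For Q80 and Q111 at 10 months 2 of 25 reached 4 genes (highest others 35 and 45). Chance cannot be excluded there either, and these splits too point to a structure of the samples. Where 0 genes were called, all 25 of 25 splits gave as many, which no split could fail to do, so that it tells nothing of chance. The highest others were 0 for Q111, Q140 and Q175 and 10 for WT at 2 months, 4 for Q111 at 6 months and 1 for Q92 at 10 months. They were 50 and 0 for the sex differences at 6 and 10 months. For Q20 with age 1 of 21 splits, the real one, gave as many as 3234 genes (highest other 438). This is the lowest share that 21 splits allow and by itself does not exclude chance. Age and the run of library numbers cannot be told apart by such splits.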
